A study of Strongylocentrotus purpuratus with 2 samples.

How the data were processed

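Whole embryos of the purple sea urchin Strongylocentrotus purpuratus were collected 30 hours after fertilization from cultures at 15 °C, with about 1000 embryos per sample. RNA was sequenced from 1 library of embryos given the glycerol control and 1 library of embryos given a morpholino, an antisense oligonucleotide, against soxC. Groups were taken from the sample titles. With 1 library per group there was no measure of the spread between samples, so no test between the conditions and no replicate check was possible, and no p-value is given for a gene or list.

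The deposited value per transcript model is a normalized signal. CASAVA 1.8 and Bowtie are named per the submitters' processing notes. The Bowtie version, the counting tool, the normalization method and the genome build are not given in the sources used here. Both column headers carry the same barcode and lane text, and whether the libraries shared a lane was not settled. Each table has 24565 rows for 17269 transcript models, because a model that overlaps several gene predictions is repeated with the same value. Values were present for 12943 models. The other 4326 models were blank in both libraries, and these include genes that every cell uses, so a blank was treated as missing and never as 0. Of the models with a value, 3006 stand on more than 1 row, and their gene names cannot be separated. Models of related genes can share reads, and neither the counting rule nor its use of strand was known.

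The deposited signal was a whole multiple of a fixed step within each library, 2.65 in the glycerol control and 2.54 in the library labelled SoxC morpholino. Division by the step gave a whole number of reads within a tolerance of 0.1 for 99.961% and 99.954% of the models. The recovered totals were 4414503 and 4763993 reads. The plan, fixed before the data were examined, had separate wording for counts and for normalized values. The deposited scaling was kept as the main one, while the level floor, pseudocount and intervals used the recovered reads. Gene names and model identifiers came from the deposited tables. None of the identifiers matched the name table at hand, so no positions are given.

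The log2 ratio of the library labelled SoxC morpholino over the glycerol control was computed with a pseudocount of 0.5 reads, which understates the change of models with few reads. Fold values were computed without it. Each ratio has an exact Clopper-Pearson 95% interval from the 2 read counts. The reads are not known to be independent molecules, so intervals and floors cover counting error only. A model met the size rule when its mean level was at least 1 CPM of recovered reads, its ratio was at least 2-fold and its interval excluded a ratio of 1. A fold against a library with 0 reads was computed against a floor of 3 reads in that library. This floor leaves out counting error in the other library, so the bound of the exact interval, which is smaller, is given beside it. To show what counting error alone gives, the reads of each model were drawn 100 times from a single common ratio and passed through the same rule.

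The 16 gene lists were fixed before the data were examined. Their entries were matched to names in the tables afterwards, when the values of some genes had already been seen. Of these names, 38 were chosen by hand, and 41 entries had no matching name. Where several models carried a name, the model with the most reads over both libraries was used. Because the median log2 ratio of all measured models was -0.21, list medians are given relative to that median, and the values without this subtraction are listed with the alternatives. Each list median was placed among 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the 2 libraries. Random members were drawn independently of each other, so the percentiles take no account of genes in a list that vary together. An extreme percentile therefore does not separate the morpholino from any other difference between the samples. Some lists share members, so their percentiles are not independent. For example, Sp-Prox1 is a neurogenesis regulator and a pigment and blastocoelar cell gene, and Sp-delta and Sp-Notch are also in the Notch pathway list.

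The named genes followed a rule fixed before the data were examined. It took soxC first, then the 10 highest and 10 lowest models with a descriptive name among those meeting the size rule, ranked by the interval bound nearest 0. It then took up to 4 list members per direction that met the rule, and the measured neurogenesis regulators in full. Names outside this rule are marked as chosen after their values were seen.

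The alternatives fixed in advance were total reads, the median of ratios and the upper quartile as scalings, a floor of 5 or none, folds of 1.5 and 3, the fold alone, pseudocounts of 0.1 and 2, and random lists not matched on level. TMM factors from edgeR 4.0.16 in R 4.3.3 on the recovered reads, totals without the most abundant model and an exact binomial test on the reads were added after the data were seen. Calculations used Python 3.11.15 with numpy, scipy and pandas. The steps were tested on simulated libraries of 8763 measured models, of which 200 were changed. The rule called 82% and 76% of models changed 2.5-fold higher and lower, and 94% and 98% of those changed 4-fold. It also called 92 unchanged models, and 96.1% of intervals for unchanged models held a ratio of 1.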

Results

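Transcript levels were measured by RNA sequencing of whole purple sea urchin embryos at 30 hours after fertilization. The libraries compared were 1 glycerol control with 4414503 recovered reads and 1 labelled SoxC morpholino with 4763993. The comparison asks which transcripts differ when a morpholino is directed against soxC, a gene for a SoxC family transcription factor. No library came from embryos given a control morpholino. Effects of targeting soxC therefore cannot be told apart from effects that any morpholino might have. With 1 library per group, they also cannot be told apart from a difference in culture, stage or preparation between the samples. There were no replicates, so each difference below lies between these 2 libraries, and intervals in parentheses are 95% counting intervals of the ratio.

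The soxC transcript itself (Sp-SoxC, WHL22.622787.0) was higher in the library labelled SoxC morpholino, at 38052.2 normalized units against 10632.2 in the glycerol control. The ratio was 3.58-fold (3.46 to 3.71), from 14959 and 4016 reads, and ranked first of the 58 higher models by its interval bound. A morpholino acts on translation or splicing and need not lower its target's transcript, so this value does not check the sample labels. Every direction given here rests on the labels.

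In the library labelled SoxC morpholino, 58 of 8819 measured transcript models were higher and 412 were lower by the size rule. Transcripts of several genes of the neurogenesis regulator list were among the lowest, led by Sp-z167, Sp-Brn1-2-4 and Sp-Otp. The RNA came from whole embryos, so the cells in which these transcripts differed are not known. The median log2 ratio of all measured models was -0.21, and the 25th and 75th percentiles were -0.49 and 0.05. With that median set to 0, 135 models were higher and 207 were lower, so the share of lower models went from 87.7% to 60.5%. Counting error around a single common ratio gave on average 18.15 higher and 119.41 lower models as deposited, and 47.5 and 46.35 with the median set to 0. The most abundant model in both libraries, WHL22.598028.0, which has no gene name, was 3.01-fold higher (2.99 to 3.02), from 298102 and 932435 reads. Many of the models that met the rule had few reads: among the 4567 models with at least 100 reads over both libraries, 9 were higher and 62 lower.

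**Figure D1:**
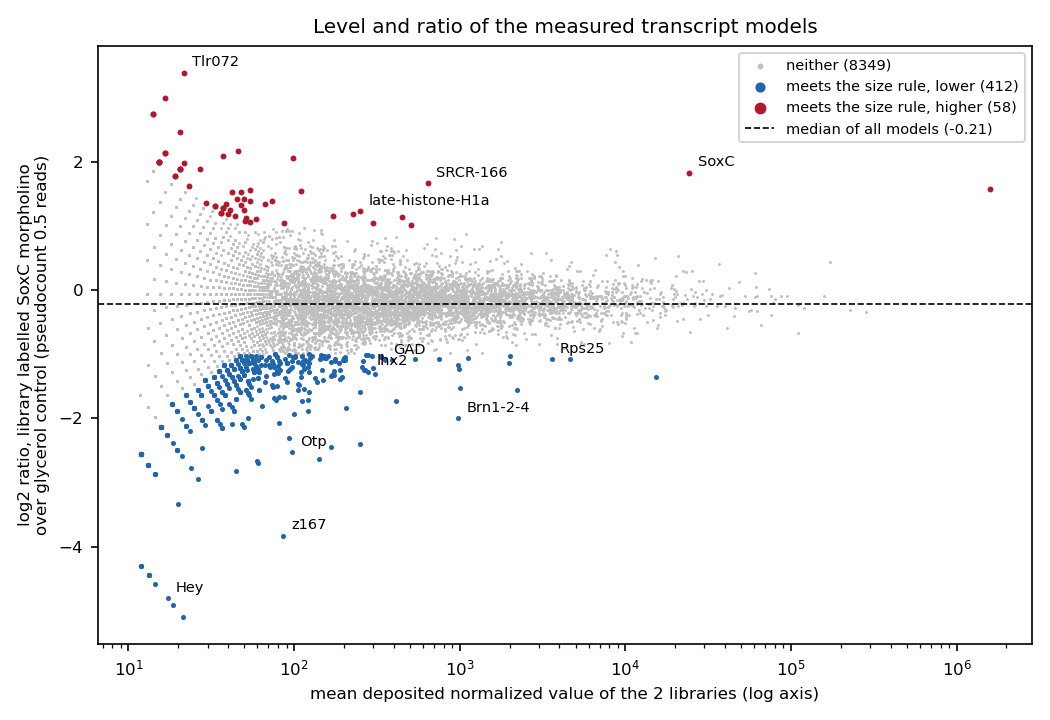
Each point is a measured transcript model, with the mean deposited normalized value of the 2 libraries on a log axis and the log2 ratio of the library labelled SoxC morpholino over the glycerol control on the other axis. The 58 higher models are red, the 412 lower models are blue, and the dashed line is the median of -0.21. The most abundant model, the unnamed WHL22.598028.0, is the red point at the far right, SoxC is the next most abundant model meeting the rule, and 370 of the 470 models meeting it have a mean value below 100.

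After soxC, the highest named model was Sp-SRCR-166, of the scavenger receptor cysteine-rich family, at 3.19-fold (2.58 to 3.96). Sp-VWD mucin-like was 4.32-fold higher (2.4 to 8.36), Sp-AmotL 2.97-fold (1.79 to 5.12) and the zinc finger gene Sp-z415 2.23-fold (1.77 to 2.83). Immune receptor models of large gene families were also present: Sp-Tlr072, a Toll-like receptor, had 1 read in the control and 16 in the other library, a ratio of 15.4 (2.39 to 645), and Sp-NLR-74 was 4.8-fold higher (1.97 to 14.1). Near-identical copies could share these reads, so the assignment to single genes is uncertain. Sp-Aass was 4.61-fold higher (1.72 to 15.5), from 5 and 24 reads. Sp-STAT had 1 and 12 reads, a ratio of 11.5 (1.71 to 493). The remaining gene of the 10 highest was Sp-late-histone-H1a, described with the histones.

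Among the 10 lowest named models, Sp-z167, a zinc finger gene, was 15.9-fold lower in the library labelled SoxC morpholino (5.89 to 60.1), from 61 and 4 reads. The POU domain gene Sp-Brn1-2-4 was 3.97-fold lower (3.32 to 4.77), from 591 and 155 reads, and the homeobox gene Sp-Otp 5.96-fold lower (3.12 to 12.5), from 63 and 11. Sp-reeler/ring was 6.38-fold lower (3.68 to 11.9) and Sp-actin putative homolog 6 was 5.57-fold lower (3.43 to 9.48). Sp-Slc7a11, named for a cystine transporter, was 6.94-fold lower (2.92 to 20), and Sp-Galnt14L 6.76-fold lower (2.84 to 19.6). In the same group, 3 models had no read in the library labelled SoxC morpholino: Sp-Galr2L_14, Sp-Mipep and Sp-Hey, from 16, 14 and 13 control reads. Against a floor of 3 reads they were at least 5.55-fold, 4.86-fold and 4.51-fold lower, while their counting intervals, which also cover error in the control reads, reach down to 4.01-fold, 3.45-fold and 3.17-fold.

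Of 17 measured neurogenesis regulators, 4 were lower by the size rule, 1 (soxC) was higher and 12 met neither. The list median was -0.19 relative to all measured models, at the 0.35th percentile of matched random lists, and at the 4.22th percentile of lists not matched on level. Besides Sp-z167, Sp-Brn1-2-4 and Sp-Otp, the LIM homeobox model Sp-lhx2, which also carries the name Sp-Lim-containing1, was 2.42-fold lower (1.8 to 3.3). The following values are log2 ratios relative to the median of all models, for members that did not meet the rule. Sp-Ptf1a was at -0.65, Sp-delta, the gene of a Notch ligand, at -0.46, Sp-Myt1 and Sp-Ato both at -0.36, and Sp-Isl at -0.19. Sp-Soxb1 was at 0.01, Sp-Soxb2 at -0.01, Sp-Notch at -0.07 and Sp-Hbn at 0.13. Sp-Ac-sc was at 0.43, Sp-Prox1 at 0.42 and Sp-rx at 0.41. Sp-Scratch, Sp-Mbx1 and Sp-POU4F2 were below the level floor.

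**Figure D2:**
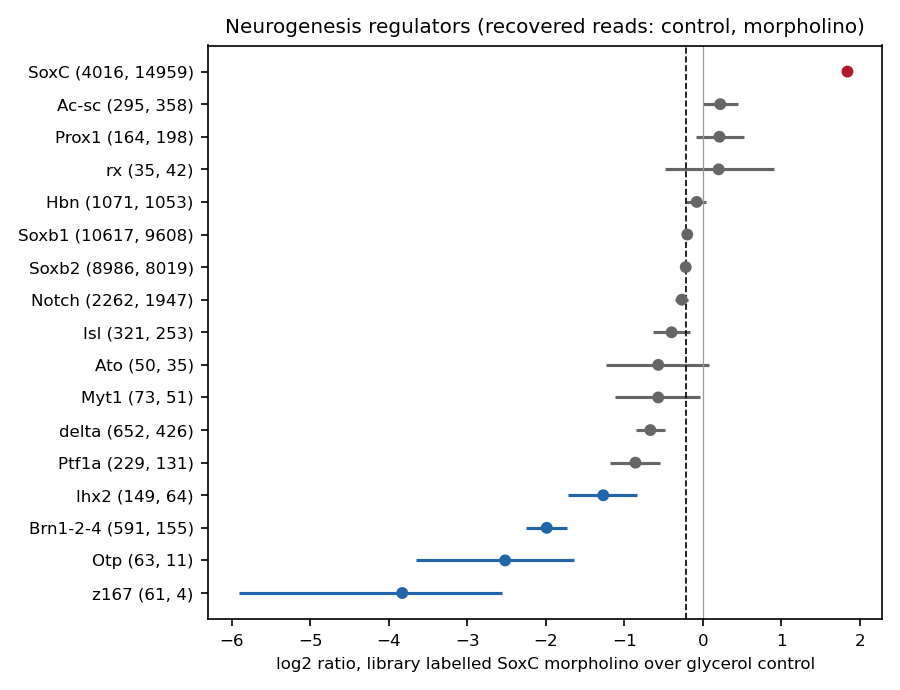
Log2 ratios of the 17 measured neurogenesis regulators, library labelled SoxC morpholino over glycerol control, with 95% counting intervals as lines and the recovered reads of the control and then the morpholino library after each name. The dashed line is the median of all models at -0.21. Blue marks the 4 lower members and red marks SoxC.

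Genes for products of differentiated neurons were thinly covered. Of 8 measured members, 2 were lower by the size rule and 6 met neither. The vesicular acetylcholine transporter model Sp-VAChT was 2.6-fold lower (1.6 to 4.37), from 60 and 24 reads. Sp-ChAT, another cholinergic model named here after its value was seen, had 9 reads in each library. Its log2 ratio relative to the median of all models was 0.15. Sp-VAChT (WHL22.544208.1) and Sp-ChAT (WHL22.544208.0) share an identifier stem. How reads were divided between these models is not known, so they may not be independent measurements. Glutamate decarboxylase, Sp-GAD, was 2.14-fold lower (1.65 to 2.79), and fell short of 2-fold with the median of all models set to 0. Of the 8 members, 4 lay above the median of all models and 4 below. The list median was -0.03 relative to all models, at the 47.93th percentile, while with a floor of 5 CPM the percentile was 0.33. Only Sp-VAChT, Sp-GAD, Sp-Syt1-2 and Sp-Snap25 lie above that floor, the last at a relative log2 ratio of 0.39. Sp-Syt1-2 and Sp-Snap25 are named here after their values were seen. Of 15 measured anterior neuroectoderm genes, 1 was lower, Sp-Otx at 2.6-fold (1.21 to 6.07) from 25 and 10 reads, and the list median was 0.07, at the 67.82th percentile. In the Notch pathway list, 1 of 10 members was lower, Sp-Hey, a transcriptional repressor gene, and the median was -0.15, at the 8.31th percentile. With the median of all models set to 0, 1 member of this list also met the rule as higher.

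Mesodermal lists lay higher in the library labelled SoxC morpholino, although none of their members met the size rule. The 10 measured pigment and blastocoelar cell genes were all above the median of all models, and the list median was 0.39 relative to it, above all 10000 matched random lists. The genes named in this paragraph fall outside the naming rule and were chosen after their values were seen. Relative log2 ratios ran from 0.21 for Sp-GataC to 0.86 for Sp-Scl. They were 0.65 for Sp-Ployketide_synthase_like, a pigment synthesis gene, and 0.52 for Sp-gcm, a regulator of pigment cell specification. The 12 skeletogenic mesenchyme genes had a relative median of 0.27, at the 99.49th percentile. Within them, the highest measured member was the spicule matrix gene SpSM29 at 0.67 and the lowest the transcription factor gene Sp-Tbr at -0.62. Both lists are described relative to the other models, since the deposited scaling places their medians at 0.18 and 0.06.

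Of 15 measured endoderm genes, 1 was lower and 14 met neither. The list median was -0.16 relative to all models, at the 1.14th percentile, but at the 8.82th percentile of unmatched random lists and the 3.72th with a floor of 5 CPM. The ParaHox gene Sp-Xlox was 2.02-fold lower (1.3 to 3.19), and met the rule under the deposited scaling and total reads but not under the other scalings. None of the 9 oral ectoderm genes met the size rule, and their relative median was 0.25, at the 98.5th percentile, or the 95.06th against unmatched lists. None of the 10 aboral ectoderm genes met it either, with a relative median of -0.02 at the 21.28th percentile. The 2 ciliary band genes met neither direction, with a relative median of -0.03 at the 36.47th percentile. Of 11 motile cilia genes, 1 was lower, the model named both Sp-Rfx2 and Sp-Rfx3, at 2.08-fold (1.38 to 3.18), and it too fell short of 2-fold with the median set to 0. The motile cilia median was 0.05, at the 58.38th percentile.

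Transcripts of cytoplasmic ribosomal protein genes were lower as a group. Of 63 measured members, 60 lay below the median of all models, 4 were lower by the size rule and 59 met neither. The relative median was -0.26, below all 10000 matched random lists, whose central 95% ran from -0.03 to 0.1. Genes of such a set can vary together, which independently drawn lists do not reproduce. Sp-Rps25 was 2.09-fold lower (1.93 to 2.27), Sp-RPL30 2.07-fold (1.79 to 2.39), Sp-Rpl10a 2.43-fold (1.37 to 4.48) and Sp-Rps20 2.74-fold (1.33 to 6.09). With the median of all models set to 0, 2 of the 4 still met the rule.

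Of 27 measured histone models, 3 were higher and 24 met neither, and 7 were higher with the median of all models set to 0. The relative median was 0.26, at the 99.39th percentile. The 3 were late histone models, forms used in later embryos. Sp-late-histone-H1a was 2.37-fold higher (1.72 to 3.29), from 56 and 138 reads. Sp-late-Histone-H2ad was 2.71-fold higher (1.32 to 5.97), from 11 and 31, and Sp-late-Histone-H4e 2.2-fold (1.14 to 4.45), from 14 and 32. Each of these 3 models carries the names of several near-identical genes. Some of the other histone models also carry the name of a gene that is not a histone. The 14 cell cycle genes had a relative median of 0.16 at the 95.23th percentile, or the 99.07th with a floor of 5 CPM. Of these, 1 was lower, the replication helicase subunit gene Sp-MCM6 at 4.37-fold (1.6 to 14.8) from 21 and 5 reads. Other subunit genes with more reads, named here after their values were seen, did not meet the rule. Sp-MCM5 was 1.41-fold lower (1.12 to 1.78), from 179 and 132 reads, and MCM2 1.08-fold (0.965 to 1.22), from 594 and 570. None of the 5 early blastula genes met the rule, with a relative median of 0.26 at the 93.98th percentile. In this list, 3 members lay above the median of all models and 2 below. The highest was Sp-Ets4 at 0.82, named here after its value was seen. None of the 10 p53 and stress response genes met the rule either, with a relative median of 0.15 at the 88.94th percentile.

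**Figure D3:**
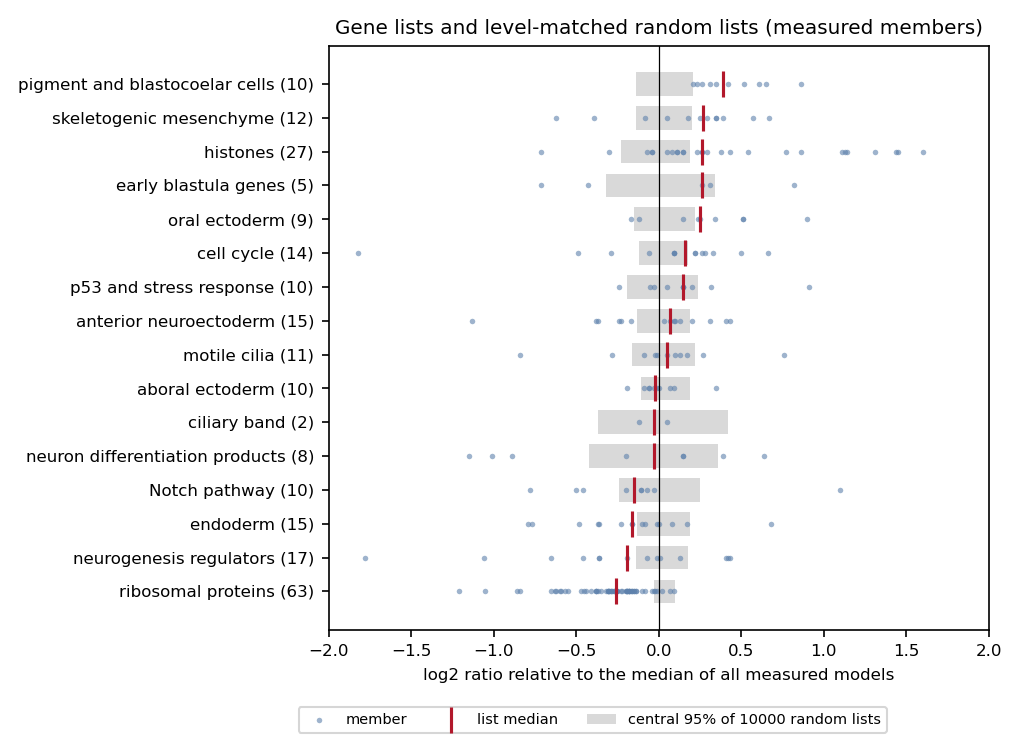
Log2 ratios of list members relative to the median of all measured models, with each list's median in red and the central 95% of 10000 level-matched random lists in grey. The number of measured members follows each list name, and 4 points lie beyond the axis limits of -2 and 2. Ribosomal protein genes have a median of -0.26 and pigment and blastocoelar cell genes a median of 0.39.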

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

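Totals without the most abundant model, TMM factors, the exact binomial test, soxC left out of its list, and list percentiles and relative medians under other floors and pseudocounts were chosen after the data were seen. The counts of models depend on the scaling and the rule. Against 58 higher and 412 lower, the median of ratios gave 135 and 207, the upper quartile 136 and 207, TMM 137 and 207, and totals without the most abundant model 115 and 239. A floor of 5 CPM gave 14 and 152, 1.5-fold 142 and 870, 3-fold 25 and 157, and the fold alone 173 and 706. An exact binomial test on the recovered reads (whole within 0.1 for 99.961% and 99.954% of models), Benjamini-Hochberg adjusted, in place of the interval called 28 and 247; it compares these 2 libraries, not the conditions. Total reads, no floor and both other pseudocounts kept both counts within 1.5 times. All 58 higher and 207 of the 412 lower models met the rule under the median of ratios, and 28 of the 33 named genes did. The 5 others were Sp-GAD, Sp-Rfx3, Sp-Xlox, Sp-Rps25 and Sp-RPL30.

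As deposited, without subtraction of the overall median, list medians were -0.40 for neurogenesis regulators, -0.14 for anterior neuroectoderm, -0.23 for neuron differentiation products, -0.36 for the Notch pathway, -0.24 for ciliary band, -0.16 for motile cilia, 0.06 for skeletogenic mesenchyme, 0.18 for pigment and blastocoelar cells, -0.36 for endoderm, 0.04 for oral ectoderm, -0.23 for aboral ectoderm, 0.05 for early blastula genes, -0.05 for cell cycle, -0.06 for p53 and stress response, -0.47 for ribosomal proteins and 0.05 for histones. They moved with the scaling. With the median of ratios they were -0.19 for neurogenesis regulators, 0.07 for anterior neuroectoderm, -0.15 for the Notch pathway, -0.03 for ciliary band, 0.05 for motile cilia, 0.27 for skeletogenic mesenchyme, 0.39 for pigment and blastocoelar cells, -0.16 for endoderm, 0.25 for oral ectoderm, -0.02 for aboral ectoderm, 0.26 for early blastula genes, 0.16 for cell cycle, 0.15 for p53 and stress response and -0.26 for ribosomal proteins. With the upper quartile they were -0.19, 0.07, -0.15, -0.03, 0.05, 0.27, 0.39, -0.15, 0.25, -0.02, 0.26, 0.16, 0.15 and -0.26 in that order. With total reads, endoderm was at -0.42, aboral ectoderm at -0.28, ribosomal proteins at -0.52, and oral ectoderm changed sign from 0.04 to -0.01. Scaling moves every model alike, so medians relative to all models and percentiles cannot move with it. All 65 relative medians under other floors, pseudocounts or without soxC stayed within counting error. That check does not cover the change of members that another floor or leaving out soxC brings. The widest move was in neuron differentiation products, from -0.03 to -0.56 with a floor of 5. The counting interval of this list's median as deposited was wide, from -0.94 to -0.01, so staying within it shows little. Percentiles entered or left the central 95% of random lists in 6 cases: unmatched lists gave 4.22 for neurogenesis regulators, 8.82 for endoderm and 95.06 for oral ectoderm, and a floor of 5 gave 0.33 for neuron differentiation products, 3.72 for endoderm and 99.07 for cell cycle. The cause of these 6 changes was not tested. Of 336 log2 ratios of named genes under other settings, 33 left their counting interval, mostly in genes with many reads. No paired analysis was possible because each group has 1 library.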

Other observations

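The tests in this part were chosen after the values were seen, except that the percentile of the ribosomal protein list and 3 of the other scalings of soxC had been fixed in advance. Further models outside the fixed lists or unmatched in them, most named for developmental regulators, were lower in the library labelled SoxC morpholino. They are named here because of their values. Sp-IA-1, whose name belongs to the insm1 type of zinc finger gene, was 3.33-fold lower (95% counting interval 2.56 to 4.38), from 240 and 75 reads. Sp-FoxD was 3.04-fold lower (2.18 to 4.29), Sp-Hb9 3.6-fold (1.8 to 7.8), Sp-lox 2.86-fold (1.58 to 5.43) and Sp-Sim 3.3-fold (1.27 to 10.1), the last from 19 and 6 reads. The name Sp-lox alone does not show whether that model is a regulator, and the ParaHox gene was matched to another model, Sp-Xlox. Sp-Nkx6-1 had 10 and 2 reads, 5.2-fold lower (1.11 to 48.8), and no longer met the size rule with the median of all models set to 0, while the other 5 did. Other models outside the lists were also looked at early. Sp-Cntnap4L was 4.61-fold lower (1.99 to 12.4). Sp-AN-like2 was 1.47-fold higher (1.4 to 1.54) and Sp-mmp18/19-like2 1.44-fold higher (1.4 to 1.49), and neither met the size rule.

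Gene families were found by a scan of 271 overlapping name stems with at least 7 measured models, of which 9 lay below and 11 above the central 95% of random lists. Chance alone would place 5% outside that range, 13.6 stems against the 20 seen, so most of these stems could be there by chance. The families below were picked from this scan. The 7 CCT chaperonin models, subunits of a complex that folds actin and tubulin, all lay below the median of all models, with a relative median of -0.59, at the 0.06th percentile of level-matched random lists, and 3 lower by the size rule. The 48 cytochrome P450 models had a relative median of -0.26, at the 0.01th percentile, with 3 lower. In the other direction, 16 late histone models had a relative median of 0.81, above all 10000 random lists. These late histone models are a part of the fixed histone list, including its 3 higher models, so they are not a separate result. The 15 axonemal dynein heavy chain models had a relative median of 0.31, at the 99.26th percentile, and the 22 NLR immune receptor models 0.35, at the 99.56th. These percentiles take no account of the number of stems scanned. NLR and histone genes are large families of near-identical copies, so their reads cannot be assigned to single genes.

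Ribosomal protein transcripts had a median of -0.26 relative to all models, a difference that scaling cannot give by construction, since it moves every model alike. A trend with abundance would place it within level-matched random lists, and its percentile was 0.0. Loss of short transcripts stays open, since lengths of the models were not at hand: 63 genes of the proteasome, respiratory chain and mitochondrial ribosome had a relative median of -0.07. A difference in growth between the embryos, or between preparations of single libraries, was not tested and may also account for it.

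The soxC transcript was higher in the library labelled SoxC morpholino. Scaling does not account for this, since the lowest log2 ratio over 6 scalings was 1.79. Exchanged labels cannot be told apart from a true increase: they would turn the log2 ratio to -1.84, and the labels give no independent marker of either library. SoxC protein was not measured here, and no biological explanation was tested.

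More models were lower than higher, and the median of all models was below 0. A single unnamed model (WHL22.598028.0, repeated on 16 rows) took 6.753% of the control reads (exact 95% interval 6.729 to 6.776) and 19.57% of the others (19.54 to 19.61). With scaling by total reads, leaving it out brought the median log2 ratio from -0.26 to -0.05, so its reads may account for most of the shift. The number lower over the number higher went from 9.51 to 2.08, which lay below the highest ratio of 2.52 in 100 draws with counting error alone, while the difference of 124 models lay above the highest of 45, so whether it accounts for the whole excess cannot be told apart from other causes. Earlier versions of this test gave opposite answers: a ratio of 1.53 with the median of ratios, set against a limit of 1.5, went against it, and the ratio of 2.08 set against the draws alone went for it. Counting error alone gave at most 141 lower models against 412.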
